A study of Homo sapiens with 4 samples.

How the data were processed

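Polyadenylated RNA from Jurkat cells, an established human leukemia line of T lymphocyte origin, was profiled in 4 libraries. Of these, 1 was labelled Control and 3 were labelled SLEAR shRNA with the numbers 1 to 3. Per the labels' protocols, hairpins against SLEAR were delivered with a lentiviral vector, and libraries were made by MAPS, a multiplexed method that reads the 3' ends next to the poly(A) tail, on an Illumina HiSeq 2500. The labels do not say whether the numbers 1 to 3 stand for different hairpins or for repeats of 1 hairpin, nor whether the libraries came from separate cultures. The p-values below therefore measure only the spread between these libraries, which may be technical.

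The deposited table gave a value in RPM, a read number scaled to the library total, for each of 16328 transcript rows in each library. The submitters' processing notes name FastQC, Bowtie2, SAMtools and the genome build hg19, without versions. How reads were assigned to transcript rows, how reads shared by several rows were divided, and whether rows were filtered is not given in the sources used here. In 8 rows the table gave no gene symbol, and an accession of 16085 rows was found in the reference table of gene names. Rows with identical values in every library and a mean of at least 1 RPM were merged, which removed 177 rows and left 16151. No row matched the name SLEAR or an alias of it, so the targeted transcript is not analysed here and the extent of the knockdown was not checked. No coordinates are given, because the reference annotation at hand was of another build than hg19.

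The depth of each library was estimated from the step between low values, which is what 1 read is worth. This gave about 8384889 reads for Control and 7048620, 7524253 and 4814166 for SLEAR shRNA-1, SLEAR shRNA-2 and SLEAR shRNA-3. Of the values above 0, 96.8%, 96.6%, 96.4% and 96.8% were whole multiples of that step within 0.05 reads, but 15, 24, 28 and 5 rows lay below 1 read. The values were therefore not treated as counts. The columns summed to 85.3%, 89.5%, 88.1% and 88.9% of the total that the unit implies, so part of each library's total lies outside these rows. By counting of reads alone, a value of 0 allows a level of up to 3 reads, which is 0.358 RPM in Control and 0.426, 0.399 and 0.623 RPM in the 3 SLEAR shRNA libraries. No use of molecular identifiers is stated, and for SLEAR shRNA-3 this limit is too low, since 26.7% of rows at 4 to 8 RPM and 9.21% at 8 to 16 RPM in SLEAR shRNA-1 and -2 were at 0 there.

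The choices of test, gene lists and named genes were made before the data were examined, with 1 plan for counts and another for normalized values; the plan for normalized values was used. SLEAR shRNA was compared with Control by the limma-trend method (limma 3.58.1 in R 4.3.3) on log2(RPM + 1), for 12350 rows with at least 1 RPM in at least 1 library, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 Control library, the residual spread came from the 3 SLEAR shRNA libraries, with 2 degrees of freedom, and the Control was assumed to vary like them. A fold change on the log2(RPM + 1) scale understates the change of rows with low values. Of 27 gene lists, 24 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The lists covered apoptosis, p53, interferon, NF-kB, T cell, cell cycle, ribosomal, metabolic, stress, lupus-associated, RNA-binding and histone genes, and markers of 5 other cell types.

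Named genes were those past the threshold with a mean log2 value of at least 4 and the same direction in all 3 SLEAR shRNA libraries, up to 12 in each direction. Where fewer passed, those with the smallest unadjusted p filled each direction to 6. To these were added the 4 members of each list with the smallest p and genes fixed in advance, among them BCL2, BCL2L1, MCL1, BAX, FAS, ILF2, HNRNPF and TAF15. From the fit without SLEAR shRNA-3, which was added after the data were seen, the 12 largest increases and decreases among the rows past the threshold were named too, whatever their direction in SLEAR shRNA-3. BCL2, BAX, NFATC1, ELK4, MLLT10, MSI2 and SRI were each spread over 2 rows and TPM1 over 3, and the values of 1 row are given, with the second row added for BCL2 and NFATC1. Some genes that these rules name are not reported here.

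The alternatives chosen in advance were other size factors, other filters, pseudocounts of 0.1 and 5, limma-voom on the estimated reads, and leaving out each SLEAR shRNA library. Chosen after the data were seen were array weights, a minimum mean log2 value of 4, robust moderation, summing the rows of a gene symbol, and 3 fits that left out SLEAR shRNA-3, of which 1 also removed a smooth trend on transcript GC content. Transcript length and GC content were taken from GENCODE 29 transcripts through their RefSeq names and used without coordinates. The test was checked on simulated data in which 200 rows were changed. All of them had a mean log2 value of at least 4, so recovery in lower rows was not measured. Control has no spread of its own and was given that of SLEAR shRNA-1 and -2. Within a library, all rows of similar level were given the same scatter. With all 4 libraries the test recovered 0% of 100 rows changed by 2-fold and 5% of 100 rows changed by 4-fold among 11519 rows. Among 4851 rows with a mean log2 value of at least 4 it recovered 0% and 6%, with 0 false calls in both. With the 3 libraries other than SLEAR shRNA-3, it recovered 74% and 98% among 11344 rows, with 17 false calls. Among the 4851 rows it then recovered 57% and 99%, with 0 false calls. These false calls hold only for a Control that varies no more than SLEAR shRNA-1 and -2, and for rows of similar level that scatter alike. Each library was also set against the other 3 with the same test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.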

Results

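Gene expression was measured in Jurkat cells, a human T cell leukemia line, that carried either a control hairpin or hairpins against SLEAR. The series title links SLEAR to systemic lupus erythematosus and to apoptosis, the programmed death of cells. There was 1 Control library and 3 SLEAR shRNA libraries, read at the 3' ends of polyadenylated transcripts, and values were RPM as deposited. Estimated depths were 8384889 reads for Control and 7048620, 7524253 and 4814166 for SLEAR shRNA-1, -2 and -3. SLEAR itself is not analysed here, so the knockdown was not checked. The Control has no replicate, and its values therefore carry no SD.

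The comparison of SLEAR shRNA with Control asks which transcripts differ when SLEAR is targeted. MDH1, the cytosolic malate dehydrogenase, was at 78.6 RPM in Control and at 260.0 ± 32.7 RPM (SD, n = 3) in the SLEAR shRNA libraries, a log2 difference of 1.71 ± 0.22 (SE). TMEM179B, a predicted membrane protein, was at 12.6 RPM against 47 ± 1.65 RPM (SD, n = 3), a log2 difference of 1.82 ± 0.27 (SE). In the other direction, CKAP2L, a protein of the mitotic spindle, was at 332 RPM in Control and 153 ± 11.9 RPM (SD, n = 3) with SLEAR shRNA, a log2 difference of -1.12 ± 0.19 (SE). None of these differences passed the test.

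Of 12350 rows tested with limma-trend, 0 were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.993. At an unadjusted p under 0.05 there were 92 higher and 239 lower rows, against 617.5 in all that chance gives. Limma-voom on the estimated reads also called 0 and 0, with 69 higher and 222 lower at an unadjusted p under 0.05. The test had little power among rows with a mean log2 value of at least 4, where all simulated changes were placed. On simulated data for all 4 libraries it recovered 0% of rows changed by 2-fold and 5% of rows changed by 4-fold. Without SLEAR shRNA-3 limma-trend called 0 and 0 (smallest adjusted p = 0.368), with 775 higher and 893 lower at an unadjusted p under 0.05, and with all libraries among the 4851 rows with a mean log2 value of at least 4 it also called 0 and 0, with 71 and 63. With both choices together, made after the data were seen, 345 rows were higher and 352 lower.

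The 6 increases and 6 decreases with the smallest p did not pass, and the agreement of the SLEAR shRNA libraries on their direction follows from that choice. HNRNPAB, an RNA-binding protein, was at 53.1 RPM in Control and 136, 130.4 and 108 RPM in SLEAR shRNA-1, -2 and -3. ARPC1B, a subunit of the Arp2/3 complex that nucleates actin, was at 164 RPM against 347, 321 and 415 RPM. REEP4, a protein of the endoplasmic reticulum, was at 83.4 RPM against 176, 166 and 216 RPM. PTPN6, the phosphatase SHP-1, which restrains antigen receptor signalling, was at 22.7 RPM against 49.9, 54.9 and 59.6 RPM. On the lower side were the zinc finger genes ZNF770, with a log2 difference of -1.01 ± 0.20 (SE), and ZNF322, with -1.21 ± 0.27 (SE). RASSF8 had a log2 difference of -0.96 ± 0.20 (SE) and MSI2, an RNA-binding protein of the Musashi family, -0.91 ± 0.20 (SE). PTMA, prothymosin alpha, was at 1170.1 RPM in Control against 674, 637 and 662 RPM, and is uncertain because it has many processed pseudogenes that can share its reads.

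**Figure D1:**
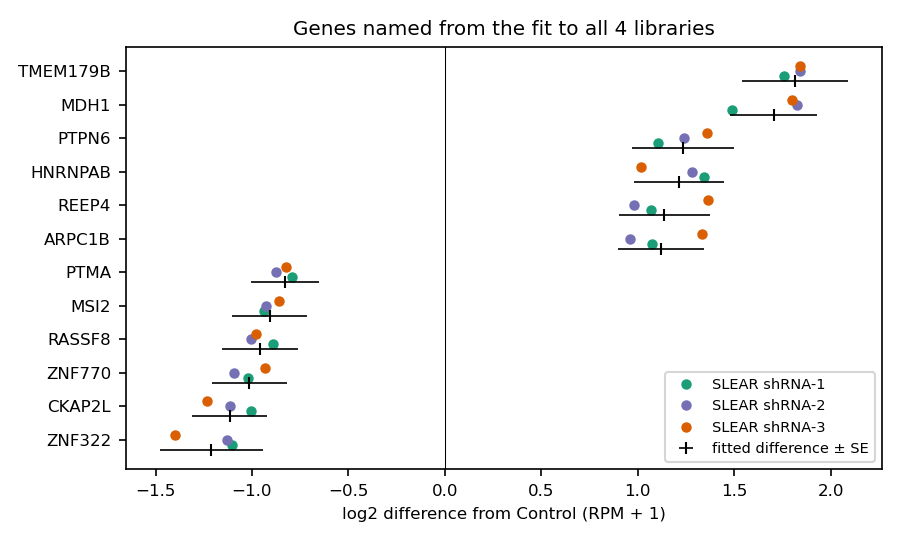
Log2 difference from Control, on RPM + 1, of the 12 genes named from the fit to all 4 libraries; each point is 1 SLEAR shRNA library, and the black mark is the fitted difference with its SE. The points of MDH1 lie at 1.49, 1.83 and 1.80 and those of CKAP2L at -1.01, -1.11 and -1.23, and none of the 12 genes passed the test.

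Apoptosis genes were examined as 3 lists. Of 27 tested anti-apoptotic genes, 7 were higher and 4 lower in all 3 SLEAR shRNA libraries, and the list did not pass (camera adjusted p = 0.363). HAX1, a mitochondrial protein that opposes cell death, was at 1269 RPM in Control and 1948, 1759.6 and 1837 RPM, DAD1 at 343 RPM against 494, 498 and 381 RPM, HSPB1, a small heat shock protein, at 95.5 RPM against 137, 138 and 114 RPM, and AVEN at 25.4 RPM against 33.6, 36.9 and 40.1 RPM. Of 26 pro-apoptotic genes, 6 were higher and 7 lower in all 3 libraries (camera adjusted p = 0.589). BID, which carries the death receptor signal to mitochondria, was at 32.8 RPM against 65.5, 55 and 97.6 RPM, and BIK at 30.4 RPM against 46.8, 48.6 and 48.4 RPM. PDCD4, at 13.2 RPM in Control, was at 5.67, 5.85 and 0 RPM, and CASP6 at 11.3 RPM against 2.98, 7.84 and 0 RPM. Of 15 death receptor genes, 0 were higher and 4 lower in all 3 libraries (camera adjusted p = 0.887), among them TNFRSF10B, a TRAIL receptor, at 59.9 RPM against 43, 39.2 and 56.9 RPM, and FADD at 121 RPM against 113, 100.1 and 82 RPM. In each of the 3 lists, 0 members passed the threshold over all rows and 0 when adjusted over the list alone. Among the members counted as lower, BIRC3, TMBIM4, BMF, CASP6, CASP10 and PDCD4 were at 0 in SLEAR shRNA-3, where a 0 is weak evidence of a fall. The counts of members that go 1 way in all 3 libraries, here and below, share 1 Control. They were not set beside the share among all rows, so they support nothing by themselves.

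The apoptosis genes fixed in advance did not pass either, and SLEAR shRNA-3 often lay apart from the other SLEAR shRNA libraries. BCL2, the founding anti-apoptotic gene of its family, was at 4.89 RPM in Control and 4.40, 7.04 and 14.7 RPM in SLEAR shRNA-1, -2 and -3, and a second, lower row of it at 2.50 RPM against 0.426, 0.133 and 0 RPM. BCL2L1 was at 36.7 RPM against 41.4, 51.3 and 37 RPM, and MCL1 at 175 RPM against 107, 139 and 188 RPM. BAX, a pore-forming effector of cell death, was at 83.7 RPM against 94.6, 95.5 and 97.7 RPM. The direction of FAS, a death receptor, turned without SLEAR shRNA-3: it was at 7.63 RPM against 5.82, 3.59 and 32.4 RPM.

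Of the 24 lists tested, 3 passed at the preset correlation. Cytosolic ribosomal protein genes rose as a list: 29 of 47 tested members were higher and 3 lower in all 3 libraries, and the median log2 differences were 0.19, 0.29 and 0.40 in SLEAR shRNA-1, -2 and -3 (camera adjusted p = 5.45e-08). With an estimated correlation the list did not pass (adjusted p = 0.765), nor by fry (p = 0.0717, adjusted p = 0.955). RPL5 was at 1212 RPM in Control and 2079, 2097 and 2298 RPM, RPL13A at 668 RPM against 1032, 1061 and 1298 RPM, RPS23 at 73.3 RPM against 116, 122 and 101 RPM, and RPL8 at 938 RPM against 1223, 1260.3 and 1290.2 RPM. Nuclear genes of oxidative phosphorylation also rose as a list, with 12 of 36 tested members higher and 3 lower in all 3 libraries (camera adjusted p = 0.00304). It did not pass with an estimated correlation (adjusted p = 0.765) or by fry (p = 0.542, adjusted p = 0.955). COX4I1, a subunit of cytochrome c oxidase, was at 774 RPM against 1155, 1263 and 1414 RPM, ATP5G1, of the ATP synthase, at 462 RPM against 795, 738 and 527 RPM, and NDUFV1, of complex I, at 58.4 RPM against 75.9, 74.4 and 87.9 RPM. The list's medians were 0.26 and 0.27 in SLEAR shRNA-1 and -2 and -0.01 in SLEAR shRNA-3. UQCRQ, near the floor at 2.15 RPM in Control, was at 0, 0.664 and 0 RPM.

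RNA-binding proteins, mainly of the HNRNP and FET families, fell as a list: 13 of 21 tested members were lower and 2 higher in all 3 libraries (camera adjusted p = 0.0375). It did not pass with an estimated correlation (adjusted p = 0.765), by fry (p = 0.259, adjusted p = 0.955), without SLEAR shRNA-1 (camera adjusted p = 0.248) or without SLEAR shRNA-3 (camera adjusted p = 0.130). HNRNPH1, a splicing regulator, was at 730.1 RPM in Control and 544, 552 and 514 RPM, and ILF2 at 63.4 RPM against 50.5, 46.9 and 46.1 RPM. HNRNPH2 was at 499.8 RPM against 316, 306 and 332 RPM, and is uncertain because its row is shared with the readthrough transcript RPL36A-HNRNPH2. TAF15, of the FET family, went against its list, at 126 RPM in Control and 197, 175 and 152 RPM. HNRNPAB, named above and not on the list, was also higher, at 53.1 RPM in Control and 136, 130.4 and 108 RPM. HNRNPF was at 3.82 RPM against 1.56, 5.58 and 0 RPM. No member of the 3 lists passed the threshold over all rows or when adjusted over the list alone. Ribosomal protein genes have processed pseudogenes that can share their reads.

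**Figure D2:**
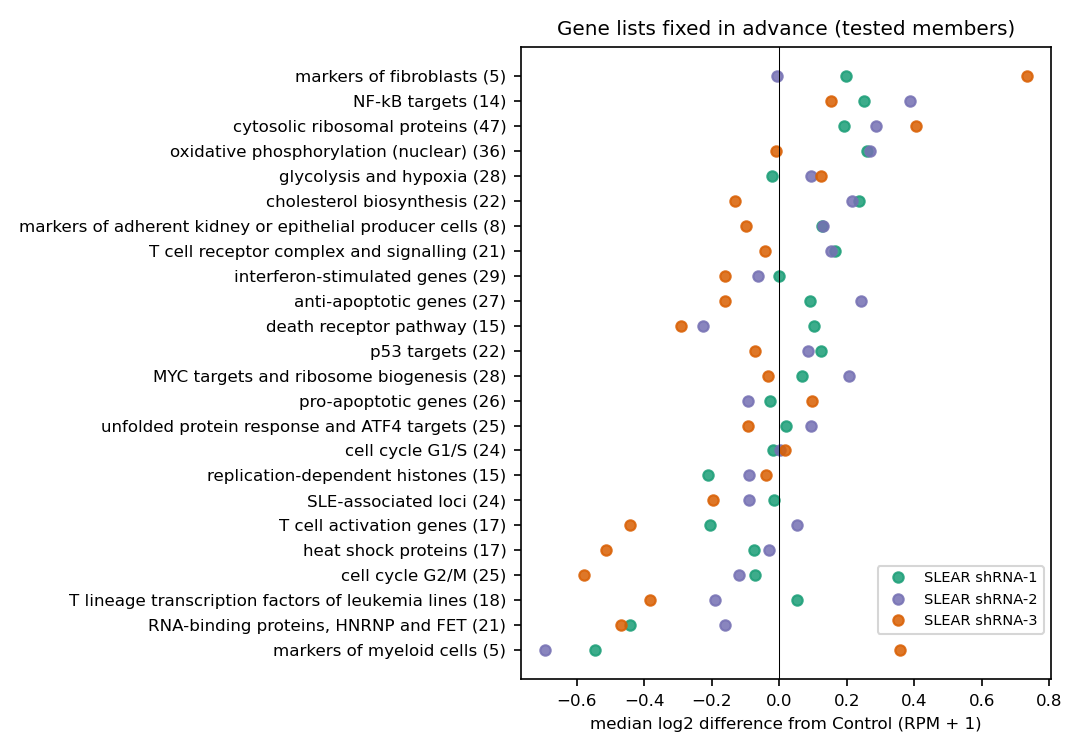
Median log2 difference from Control, on RPM + 1, over the tested members of each of 24 gene lists, with the number of members in brackets; each point is 1 SLEAR shRNA library. The points of the ribosomal list lie at 0.19, 0.29 and 0.40, and those of the RNA-binding list at -0.44, -0.16 and -0.47.

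The other lists did not pass. Among genes of glycolysis and hypoxia (28 tested, adjusted p = 0.183), the glycolytic enzymes PKM, at 352 RPM in Control and 505, 510.1 and 516 RPM, ENO1, at 166 RPM against 235, 276 and 344 RPM, and HK1, at 20.6 RPM against 37, 58.5 and 37.2 RPM, were higher in all 3 libraries, and VEGFA was near the floor. Among genes at lupus-associated loci (24 tested, adjusted p = 0.991), CSK, the kinase that holds Src family kinases inactive, was at 63.6 RPM against 109, 101 and 101 RPM, and TET3 at 32.6 RPM against 20.3, 19.7 and 21.8 RPM. Among T lineage transcription factors (18 tested, adjusted p = 0.656), DTX1, a Notch target, was at 3.70 RPM against 12.9, 11.4 and 17 RPM, TCF12 at 307 RPM against 199.8, 228 and 229 RPM, and HES1, another Notch target, at 57.1 RPM against 39, 30.8 and 31.2 RPM. Among T cell receptor and signalling genes (21 tested, adjusted p = 0.249), LCK, the kinase that starts T cell receptor signalling, was at 753 RPM against 925, 884 and 1037 RPM, CD4 at 6.68 RPM against 19.7, 14.8 and 10.8 RPM, and CD28 at 7.87 RPM against 1.28, 2.92 and 0 RPM. The p53 targets (22 tested, adjusted p = 0.887) included ZMAT3, at 41.1 RPM against 16.3, 31.5 and 14.7 RPM, and DDB2, at 43.1 RPM against 48.7, 56.9 and 67.5 RPM.

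Cell cycle genes of G1/S (24 tested, adjusted p = 0.887) included TYMS, thymidylate synthase, at 1192 RPM in Control against 934, 859 and 751 RPM. Those of G2/M (25 tested, adjusted p = 0.499) included CDC20, at 144 RPM against 189, 197 and 190.3 RPM, and BUB1B, at 161 RPM against 121, 124 and 93.9 RPM. Interferon-stimulated genes (29 tested, adjusted p = 0.887) had 5 members higher and 9 lower in all 3 libraries, among them IFITM1, at 48.3 RPM against 61.7, 69 and 73.5 RPM, and on the lower side, at low levels, RSAD2, at 1.31 RPM against 0, 0 and 0 RPM, IFI44, at 3.82 RPM against 1.42, 0.532 and 0 RPM, and IFIH1, at 7.75 RPM against 3.55, 3.06 and 0.831 RPM. Of the interferon genes counted as lower, IFI44, IFIT3, IFITM3 and RSAD2 were at 0 in SLEAR shRNA-3, where a 0 is weak evidence of a fall. MYC targets and ribosome biogenesis genes (28 tested, adjusted p = 0.419) included FBL, at 399 RPM against 501, 508 and 484 RPM. Genes of the unfolded protein response (25 tested, adjusted p = 0.887) included ATF3, at 32.2 RPM against 19.3, 19.3 and 15.8 RPM. Heat shock proteins (17 tested, adjusted p = 0.887) and replication-dependent histones (15 tested, adjusted p = 0.991) did not pass. Markers of myeloid cells and of fibroblasts (5 tested each) gave adjusted p values of 0.887, and those of adherent kidney or epithelial cells (8 tested) 0.817. B cell markers (2 tested members), erythroid markers (4 tested members) and mitochondrially encoded genes (0 tested members) were too few for a test. The median log2 difference over all tested rows was -0.11, and camera compares a list with the other rows. Camera pointed up although the list's median and mean lay below 0 for the pro-apoptotic, MYC target, G1/S, unfolded protein response, histone and myeloid lists. It also pointed up although the mean alone lay below 0 for the anti-apoptotic, death receptor, p53, interferon, T cell receptor and cholesterol lists.

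Over all rows, SLEAR shRNA-3 lay apart from the other 3 libraries. Across genes, the Pearson correlation of log2 values was 0.977 between SLEAR shRNA-1 and -2, 0.883 and 0.886 between SLEAR shRNA-3 and these, and 0.962 and 0.965 between Control and SLEAR shRNA-1 and -2. Of 16328 rows, 6941 were at 0 in SLEAR shRNA-3, against 2984 in Control, 2641 in SLEAR shRNA-1 and 2314 in SLEAR shRNA-2. Among rows at 8 to 16 RPM in SLEAR shRNA-1 and -2, 9.21% were at 0 in SLEAR shRNA-3, so a 0 in that library does not show that a transcript was near absent. Set alone against the other 3 libraries with the same limma-trend test, SLEAR shRNA-3 gave 2657 rows past the threshold, while Control, SLEAR shRNA-1 and SLEAR shRNA-2 each gave 0.

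**Figure D3:**
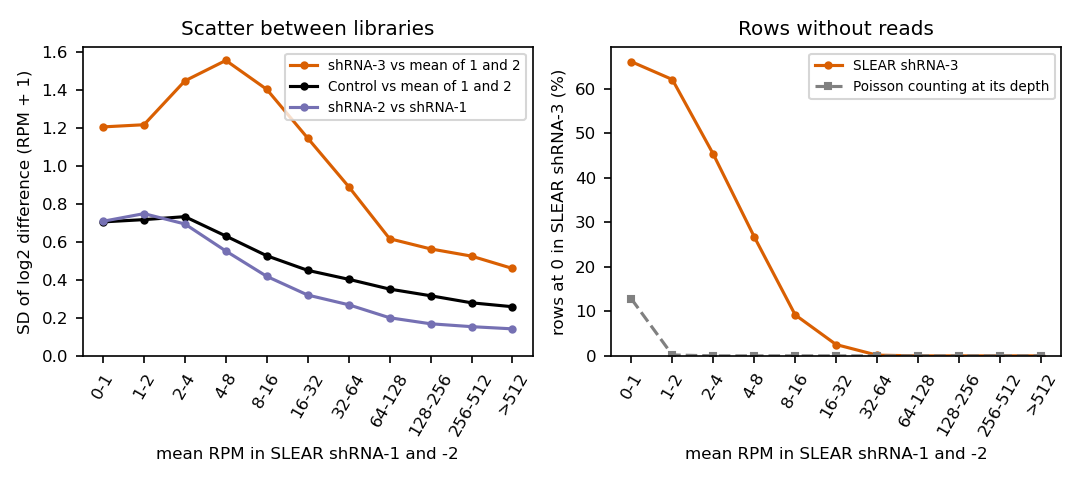
Left, SD across rows of the log2 difference (RPM + 1) between libraries, and right, percent of rows at 0 in SLEAR shRNA-3 beside the percent that Poisson counting gives at its depth, both by mean RPM in SLEAR shRNA-1 and -2. Above 512 RPM the SD was 0.46 for SLEAR shRNA-3 against the mean of the other 2 and 0.14 between those 2.

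Without SLEAR shRNA-3, and among rows with a mean log2 value of at least 4, MDH1 on the log2(RPM + 1) scale rose 3.16-fold, from 78.6 RPM to a mean of 252 RPM (n = 2), TMEM179B 3.48-fold and HNRNPAB 2.48-fold. PEX14, of the peroxisomal import machinery, rose 3.12-fold and HADHA, of mitochondrial fatty acid oxidation, 2.72-fold. XPO1, the main nuclear export receptor, fell and was 2.46-fold lower, POLR2B, a core subunit of RNA polymerase II, 2.40-fold lower and DDX18, an RNA helicase, 2.35-fold lower. ELK4, an ETS family transcription factor, was 3.41-fold lower and HBEGF, a growth factor of the EGF family, 2.39-fold lower. Some of these falls were not seen in SLEAR shRNA-3, where XPO1 was at 70.6 RPM against 78.7 RPM in Control, POLR2B at 112 RPM against 116 RPM, and ELK4, which was higher, at 176 RPM against 104 RPM.

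Of the 4851 rows in that fit, 345 were higher and 352 lower by limma-trend at an adjusted p under 0.05, of which 36 rose and 43 fell by at least 2-fold. The other large increases were in TBC1D22A (2.83-fold), TMEM63C (2.61-fold), SRI (2.52-fold), MLLT10 (2.45-fold), CSAG1 (2.45-fold) and CCDC22 (2.44-fold). The other large decreases were in CLIC4 (2.51-fold lower), SLC30A3 (2.47-fold), CDK5R1 (2.39-fold), CTC-338M12.4 (2.37-fold), SNX19 (2.36-fold) and WAPAL (2.35-fold). EIF3C, at 6.98 RPM in Control and 70, 16.1 and 58.1 RPM, and SERF1A, at 122 RPM against 11, 18.9 and 79 RPM, also passed but have near-identical gene copies and are uncertain. SLEAR shRNA-3 was left out of this fit but not of the filter, as the mean log2 value was taken over all libraries. In SLEAR shRNA-3, 520 of the 697 rows (74.6%) had the same sign and the rest did not. Agreement of sign supports nothing by itself, because the same Control is shared. Among the named genes the log2 difference of SLEAR shRNA-3 from Control had the opposite sign for ELK4 (0.76), CDK5R1 (0.50), MLLT10 (-0.13), CSAG1 (-0.04) and MCL1 (0.10). It was near 0 for POLR2B (-0.05), SNX19 (-0.13) and XPO1 (-0.15). The spread rested on 1 degree of freedom per row and was pooled over rows. This pooling was complete, with infinite prior degrees of freedom, against 2.20 over all rows, so disagreement within a row did not count against it. SLC30A3, for example, passed at 28.8 and 9.70 RPM in SLEAR shRNA-1 and -2, against 43.1 RPM in Control. By limma-voom without SLEAR shRNA-3, 53 rows were higher and 87 lower, and 131 of the 697 rows were among them. Array weights on all libraries called 0 and 0 over all rows (smallest adjusted p = 0.301, with 717 higher and 927 lower at an unadjusted p under 0.05). Among the 4851 rows they called 254 higher and 267 lower, of which 512 were among the 697. Over all rows the weight of SLEAR shRNA-3 was 0.142, so such a fit comes near to leaving that library out and is no separate support.

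Several list members passed in that fit, in which 697 of 4851 rows passed. Of 42 ribosomal protein genes with a mean log2 value of at least 4, 14 rose and 1 fell, and 19 passed when adjusted over the list alone; RPL5 rose 1.72-fold and RPL13A 1.57-fold. Of 31 oxidative phosphorylation genes 6 rose and 1 fell, with 7 adjusted over the list alone. Of 18 glycolysis and hypoxia genes 7 rose and 1 fell, with 8 adjusted over the list alone, among them HK1 (2.20-fold), ENO1 (1.53-fold) and PKM (1.44-fold). Of 13 anti-apoptotic genes 3 rose and 1 fell: HAX1 rose 1.46-fold (adjusted p = 1.28e-04, limma), DAD1 1.45-fold and HSPB1 1.43-fold, and MCL1 was 1.43-fold lower (adjusted p = 0.0200, limma) but not in SLEAR shRNA-3. Of 14 pro-apoptotic genes 2 rose and 0 fell, BID by 1.81-fold (adjusted p = 0.00126, limma) and BIK by 1.55-fold. Of 7 death receptor genes 1 rose and 0 fell, namely TNF, singled out after its values were seen, which rose 1.64-fold (adjusted p = 0.00944, limma) but in SLEAR shRNA-3 was at 18.9 RPM against 35.3 RPM in Control. Of 9 p53 targets 0 rose and 2 fell, ZMAT3 (1.78-fold lower) and XPC (1.54-fold lower). Calls among pro-apoptotic and death receptor genes were about as frequent as among all rows. By camera in that fit the anti-apoptotic (adjusted p = 0.210), pro-apoptotic (0.908), death receptor (0.908), p53 (0.822) and glycolysis (0.0801) lists did not pass. The ribosomal (1.42e-06) and oxidative phosphorylation (1.01e-04) lists passed, but not with an estimated correlation (0.938 for each). In each of the other lists at most 2 rose and at most 2 fell. Both TAF15, which rose 1.47-fold, and HNRNPH1, which was 1.33-fold lower, passed.

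Each SLEAR shRNA library was also set against the Control alone, which gives no test. Of 4851 rows, 46 were at least 2-fold higher and 69 at least 2-fold lower in SLEAR shRNA-1, 39 and 63 in SLEAR shRNA-2, and 307 and 514 in SLEAR shRNA-3. Across genes, which are not independent replicates, the log2 differences of SLEAR shRNA-1 and -2 correlated with r = 0.81, against 0.50 in simulated unchanged libraries that share the Control. The correlation was 0.27 between SLEAR shRNA-1 and -3 and 0.32 between SLEAR shRNA-2 and -3, against 0.17 simulated for each. The covariances were 0.139, 0.0911 and 0.103, against 0.0333, 0.0332 and 0.0335 simulated. The simulation gave Control the scatter seen between SLEAR shRNA-1 and -2. At 64 to 128 RPM the SD was 0.352 for Control against their mean and 0.201 between them. With 1 Control the libraries cannot be split, so part or all of the excess may come from the shared Control. The differences also followed transcript GC content across genes, with Spearman's rho of 0.31, 0.31 and 0.35 in SLEAR shRNA-1, -2 and -3, and transcript length, with rho of -0.21, -0.30 and -0.14.

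**Figure D4:**
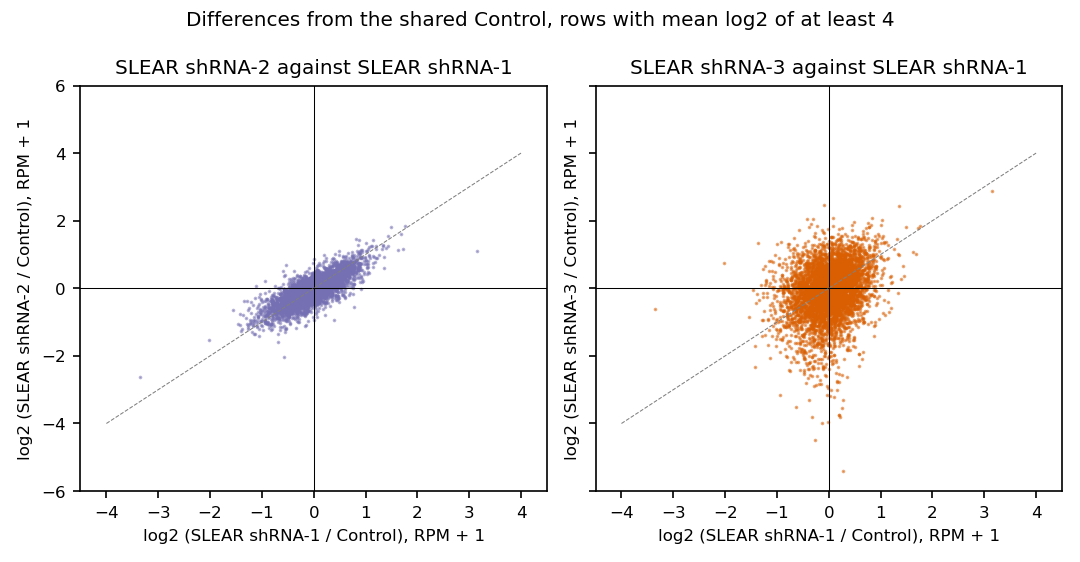
Log2 ratio to the shared Control (RPM + 1) in SLEAR shRNA-2 (left) and SLEAR shRNA-3 (right) against that in SLEAR shRNA-1, 1 point for each of 4851 rows; the dashed line marks equal values. The cloud is narrow on the left (r = 0.81) and wide on the right (r = 0.27).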

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

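There were also 0 higher and 0 lower rows under each alternative chosen before the data were examined and run: median-of-ratios and upper quartile factors, other filters, pseudocounts of 0.1 and 5, limma-voom, and without each SLEAR shRNA library. Where SLEAR shRNA-3 was included this says little, since with all 4 libraries the test recovered 5% of simulated 4-fold changes. Without SLEAR shRNA-3 and with all rows tested, it recovered 74% of simulated 2-fold and 98% of 4-fold changes. All these changes were placed in rows with a mean log2 value of at least 4, so recovery in lower rows was not measured. That simulation gave Control the scatter of SLEAR shRNA-1 and -2, and gave all rows of similar level the same scatter. In the real fit over all rows without SLEAR shRNA-3 the prior degrees of freedom were 2.20, so rows differed in scatter. These shares may therefore be too high for the data and do not measure the power of that fit. The alternatives that called rows were chosen after seeing the data: 254 higher and 267 lower with array weights among rows with a mean log2 value of at least 4, 345 and 352 there without SLEAR shRNA-3, 318 and 273 with a GC trend also removed, and 53 and 87 by limma-voom without SLEAR shRNA-3. Over all rows the weights gave SLEAR shRNA-3 0.142 and the others at least 1.53, and the cause beyond that was not tested. The number of lists that passed was 3 of 24 with all libraries, 2 to 3 without 1 library, and 5 of 20 among rows with a mean log2 value of at least 4, where those of T lineage transcription factors and of glycolysis and hypoxia joined the 3 (adjusted p = 0.0277 for each). The RNA-binding list was the one lost without SLEAR shRNA-1 (adjusted p = 0.248) or SLEAR shRNA-3 (0.130), with upper quartile factors (0.0702), without a filter (0.0719), with array weights (0.130) or with these and a mean log2 value of at least 4 (0.122), and at up to 0.420 in the added fits that left out SLEAR shRNA-3. With an estimated correlation 0 lists passed. Count tests and their scaling were not run, because the values are not counts; scaling by library size is the deposited scale itself. No paired analysis was possible because with 1 Control library the groups share fewer than 2 replicate numbers.

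Of 2405 named-gene values under the alternatives, 2186 kept their side, 207 passed the threshold and 12 changed sign. The 207 all came from fits chosen after the data were seen that left out or down-weighted SLEAR shRNA-3, and none from the alternatives chosen in advance. The 12 increases and 12 decreases named from the fit without SLEAR shRNA-3 were picked because they passed there, so their part of the 207 was fixed beforehand. Without 1 SLEAR shRNA library, the log2 difference ranged from -0.16 to 0.49 for CD68, from -0.83 to 0.0051 for EPOR, from -0.43 to 1.13 for COL6A1, from -0.11 to 1.36 for ACTA2 and from -0.63 to 0.81 for FAS. With array weights, and by limma-voom without SLEAR shRNA-3, it was -0.23 and -1.17 for COL6A1 and -0.63 and -0.74 for FAS. ACTA2 was at -0.22 with a pseudocount of 0.1 and FAS at -0.073 by limma-voom with all libraries. TPM1 was at 0.011 without SLEAR shRNA-3 and with the GC trend removed. The cause was not tested. In SLEAR shRNA-3, 3 reads are 0.623 RPM, but 26.7% of rows at 4 to 8 RPM were at 0 there, so depth is not what limits low rows in that library.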

Other observations

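Of the tests below, those on the rows at 0 and the scatter of SLEAR shRNA-3, and the splits of all 4 libraries, were chosen after the result was seen. The scatter test replaced an earlier one that rested on an assumed number of molecules and came out the same way.

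Several genes of sterol synthesis and of acute response were not described above. FDPS, farnesyl diphosphate synthase, was at 138 RPM in Control and 159.7, 199 and 264 RPM in SLEAR shRNA-1, -2 and -3, and MVD at 30.8 RPM against 41.3, 44 and 44.9 RPM. The cholesterol list of 22 tested genes did not pass (camera adjusted p = 0.499). Among 17 T cell activation genes (adjusted p = 0.887), JUN was at 13 RPM against 3.69, 5.85 and 2.91 RPM, and NFATC1 at 22.7 RPM against 25.8, 36.7 and 47.6 RPM in 1 row and at 26.6 RPM against 33.2, 26.4 and 16.4 RPM in another. Among 14 NF-kB targets (adjusted p = 0.168), NFKB2 was at 8.62 RPM against 16.9, 17.4 and 24.5 RPM, RELB at 0.954 RPM against 2.13, 2.66 and 9.35 RPM, and LTB at 28.3 RPM against 33.6, 42.8 and 31.8 RPM. None of these genes passed over all rows.

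SLEAR shRNA-3 stood apart, with many rows at 0 and a wide scatter. Lower depth is argued against, since 9.21% of rows at 8 to 16 RPM were at 0 where Poisson counting gives almost none. For none of the 5 other cell types listed were most of the tested markers raised. The highest share was 40%, namely 2 of 5 myeloid genes with FCER1G the most abundant at 13.7 RPM. Raised was judged against SLEAR shRNA-1 and -2 and not against Control, where FCER1G was at 10.5 RPM. The marker values cannot exclude cells of another type, since few markers could be tested, such as 2 of 13 for B cells and 4 of 13 for erythroid cells. LYZ, S100A9, HBB and COL1A1 were at 0 in that library, where a 0 does not show that a transcript was near absent. A smaller number of captured molecules may account for the rows at 0, as 26.7% of rows at 4 to 8 RPM were at 0 against 29.2% from the number fitted to the next bin. It does not alone account for the scatter of abundant rows, which was 1.34 times larger at 64 to 128 RPM than above 512 RPM, where sampling of molecules gives 3.31, and a difference between hairpins stays open and untested.

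The higher level of the ribosomal protein list was set against trends across genes. After removal of a trend on transcript length its median lay at percentile 99.73 of 10000 random lists, and after removal of a trend on GC content at 99.99. Among random lists matched on mean level it lay at percentile 100. These values argue against each trend as the whole cause, but reads shared with pseudogenes and a property of the single Control library stay open, as does an effect of the hairpins.

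Some rows were detected in Control and at 0 in SLEAR shRNA-1 and -2. With these 3 libraries thinned to 1 depth, 185 rows had at least 5 reads in Control and 0 in the others, against 148 and 148 for SLEAR shRNA-1 and -2, a ratio of 1.25. Before thinning the numbers were 207, 142 and 163, so thinning moved little. A small excess in Control remained at equal depth, and its sources cannot be told apart. Diffuse background reads in Control are argued against, as olfactory and similar silent gene families summed to 0.619 of the higher of SLEAR shRNA-1 and -2. That sum rests on 27 rows, with about 41 reads in Control against 56 and 55. Small RNA genes made up 10 of the 185 rows (5.41%), against 1.02% of all rows, and the cause of this was not tested.

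The splits of the libraries are too few for a share under 0.05. With all 4 libraries the real split gave 0 rows, a number that all 4 ways to set 1 library against the other 3 must reach, so their count says nothing. The highest other, SLEAR shRNA-3 against the rest, gave 2657, many more than the real split, which points to a structure of the libraries. Without SLEAR shRNA-3, 1 of 3 splits, the real one, gave as many as 697 rows, and the highest other gave 2.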
